A study of Drosophila melanogaster with 3 samples.

How the data were processed

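The material was chromatin from whole Drosophila melanogaster embryos collected 0 to 24 hours after laying. The flies carried a transgene for Mld, the zinc-finger protein of the molting defective gene, fused to eGFP. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels, and precipitated with an antibody against GFP. There were 3 samples, which the labels number as biological replicates 1, 2 and 3, and all belonged to 1 group. The labels point to a possible control experiment, which was not analysed here, so there was no comparison group.

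The deposited files were peak lists on the dm6 build, per the labels. Each sample had its own list of peaks ranked by the irreproducible discovery rate (IDR) and its own shorter list of the peaks past an IDR threshold. Further lists were deposited for the whole series. The sample records name the alignments of all 3 samples, with 2 further files, as the source of each, but not how these were pooled or paired. The aligner, the peak caller and their versions are not given in the sources used here. The deposited score of a peak was found, in the files, to equal a scaled logarithm of its global IDR, capped at 1000, with 830 as the lowest score in the thresholded lists. The deposited ranked lists also held the global IDR as a −log10 value. The deposited signal of each peak is the authors' own value per peak with no stated scaling, and it was used only to rank peaks within a list. The thresholded lists corresponded to a global IDR of at most 0.01. They lacked 66, 60 and 54 peaks of replicates 1, 2 and 3 that passed this value in the ranked lists, for a reason the sources do not state. Because the authors listed peaks per sample, per the sample records, replicates were compared by the overlap of their lists. Read numbers were not in the files, so the depth of each sample is unknown and no interval was derived from it. The intervals printed with shares are exact (Clopper-Pearson) 95% binomial intervals over regions or genes. Regions and genes are not independent replicates, and these intervals and the p-values beside them do not measure the spread between embryo collections.

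Peaks were annotated with Ensembl release 115 of the fly annotation (BDGP6.54) and the Release 6 genome sequence. The arms 2L, 2R, 3L, 3R, 4, X and Y were used. Transposable elements were left out, which left 18277 genes, 13968 of them protein-coding, and 35612 transcripts. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peaks of the 3 lists were merged where they overlapped by at least 1 bp, and merged regions with a peak from every list formed the consensus. The summit of a region was the median of the summits of its highest-signal peak in each list. Overlap of lists was compared with 10000 random placements of the shorter list within its arms in a one-sided permutation test. Summits were put into 1 of 7 classes, promoter first (within 500 bp of a transcript start), and compared with 10000 random placements in a two-sided permutation test. Arms were compared with their share of the assembled length by exact binomial tests. Gene lists were compared by two-sided Fisher's exact tests of having a consensus summit within 500 bp of a start, against all other protein-coding genes, or all other annotated genes for lists of non-coding RNA genes. Motif words were counted on either strand within 100 bp of the summit and in windows of the same width 1000 bp upstream and downstream. Upstream and downstream of a summit follow genome coordinates here, not the strand of a gene. Exact McNemar tests against each flank were run and the larger p was kept. All 7-mers were tested in the same way. Benjamini-Hochberg adjustment was applied within each family of tests, with a threshold of 0.05.

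The 19 gene lists, the 15 motif words, the main tests and most alternatives were fixed before the data were examined. So was the rule for named genes. It takes every gene of the lists of ecdysteroid synthesis and ecdysteroid gland regulators, and the 20 consensus regions with the best mean rank of signal. It also takes up to 4 genes with a summit from each list past the threshold and from the ecdysone response list. Some listed genes carry other symbols in the annotation (phm as phtm, for example), and snc had no match and was left out. The statistics were tested on simulated data. In 10 lists of 20 genes, a further 30% chance of being bound was added to the 5% given to all 13968 genes. Genes were bound independently of each other. All 10 lists were called, and 0 of 10 unchanged lists were. With peaks shared at 30% between a pair of lists of 1000 peaks, 30.4% were found shared. No motif and no 7-mer passed in 619 random windows. These windows lay anywhere on the arms, so they do not test whether sequence near gene starts differs from its flanks.

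Alternatives covered the IDR threshold, the overlap that counts as shared, leaving out each replicate, the list the authors named conservative in place of the consensus, the promoter window, the starts used, the background and the control windows. The planned IDR of 0.01 left the lists as deposited, so it tested nothing. Values of 0.001 and 0.05 were added after the data had been seen. The ranked lists of the whole series were not used here.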

Results

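The data set maps where Mld, a zinc-finger regulator known for its part in the synthesis of the steroid hormone ecdysone, was detected along the genome of whole embryos aged 0 to 24 hours. It holds 3 biological replicates of 1 group, mld-eGFP embryos, precipitated through the GFP tag. The questions the design allows are how well the replicates matched, where the shared peaks lie, which genes they adjoin and which sequence words they hold. The thresholded lists held 1461 peaks in replicate 1, 966 in replicate 2 and 1229 in replicate 3 (mean 1219 ± 248, SD, n = 3). The median peak width was 260, 244 and 344 bp in replicates 1, 2 and 3, which was also the largest width in each list. Read depth is unknown, so a missing peak is not evidence of missing binding.

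Most peaks of the shorter list in each pair were found again in the other list. Replicate 2 shared 786 of its 942 peaks on the arms with replicate 1 (83.4%, 95% interval 80.9 to 85.8) and 670 with replicate 3 (71.1%, 68.1 to 74.0). Replicate 3 shared 876 of 1223 with replicate 1 (71.6%, 69.0 to 74.1). Random placement gave means of 0.529%, 0.506% and 0.631% for these pairs, and 0 of 10000 placements reached the observed share (one-sided permutation p = 0.0001 for each pair, the smallest they can give). Merging the lists gave 1874 regions, of which 835 came from 1 list, 419 from 2 lists and 620 from all 3. These 620 consensus regions had a median width of 344 bp, which is also the largest peak width of replicate 3. The summits of the lists lay a median of 30 bp apart within a region. Across the consensus regions, Spearman's rho of the authors' signal was 0.762 between replicates 1 and 2, 0.526 between 1 and 3, and 0.559 between 2 and 3. These are correlations across regions, which are not independent replicates.

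Consensus regions lay almost entirely at gene starts. Of the 620 summits, 598 were within 500 bp of an annotated start (96.5%, 94.7 to 97.8), where random placement put 13.7%. The median distance to the nearest start was 40 bp, and 548 summits (88.4%) were within 100 bp. Introns held 14 summits (2.26%, against 39.5% at random), intergenic sequence held 6 (0.968%, against 27.0%) and 3′ UTRs held 2 (0.323%, against 4.43%). Coding exons held 0, against 13.8% at random. For these 5 classes the permutation p was 0.0001, the smallest the placements can give (adjusted p = 0.00014). Each summit had only 1 class, promoter first, so the shortfalls in the other classes largely follow from the promoter share. They are not separate results. The 5′ UTR and non-coding exon classes also held 0 summits beyond the promoter windows (adjusted permutation p = 0.0315 and 0.0225). Both calls were lost at an IDR of 0.001 and with a promoter window of 1000 bp (adjusted permutation p = 0.186 and 0.131). With protein-coding starts only, the call for 5′ UTRs was lost (adjusted permutation p = 0.107) and the non-coding exons turned to more than at random (7.58%). Among the peaks of single replicates, 92.3% ± 0.384 (SD, n = 3) were at promoters. Promoters held 81.4% (78.5 to 84.0) of the regions found in 1 list, 93.5% (90.7 to 95.7) of those in 2 lists and 96.5% of those in all 3.

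**Figure D1:**
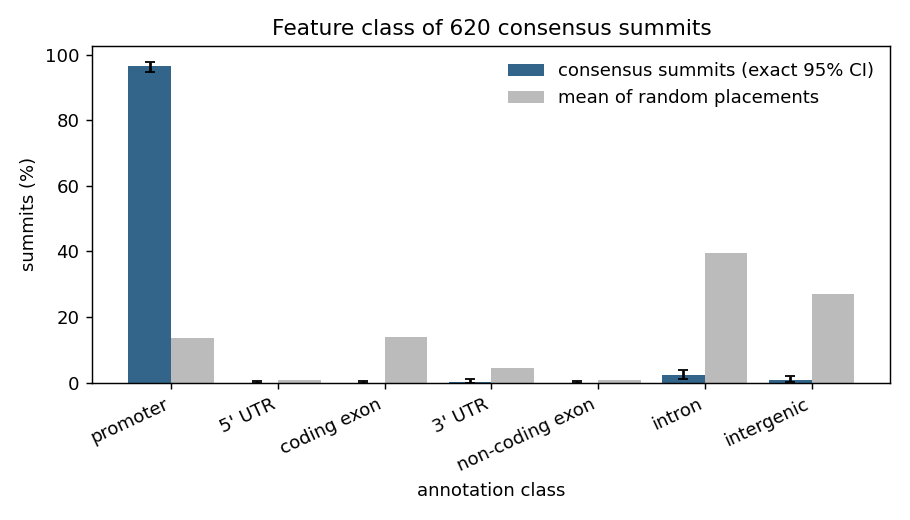
Share of consensus summits in each annotation class (vertical axis, %, blue bars with exact 95% intervals) beside the mean of the random placements (grey bars). Promoters hold 96.5% of the summits and 13.7% of the random places.

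Arm 2R carried more consensus summits than its length, and arms 3L and Y fewer. Arm 2R held 157 summits (25.3%, 21.9 to 28.9), against 18.4% of the length (exact binomial test, adjusted p = 6.94e-05). Arm 3L held 88 (14.2%, 11.5 to 17.2), against 20.4% (exact adjusted p = 0.000185), and arm Y held 0, against 2.67% (adjusted p = 8.28e-07). Arms 2L, 3R, 4 and X held 111, 151, 2 and 111 summits and did not pass. With the share of annotated starts as the expectation, which is 0.469% for arm Y, the call for Y was lost (exact adjusted p = 0.300).

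The strongest consensus region, first by signal in every replicate list, lay in an intron of org-1, which encodes a T-box transcription factor. It spans X, 8452221 to 8452514, with its summit 2496 bp from the nearest start, and its signal was 568, 468 and 408 in replicates 1, 2 and 3. The other 19 of the 20 regions with the best mean rank were at promoters. The second was at Ube3a, a ubiquitin ligase gene, and CG7600 (3L, 11210516 to 11210771). It was followed by regions at MESK2 and TAF1C-like (2R, 21501918 to 21502127) and at Rpn6, a proteasome subunit gene, with ave (2R, 14752231 to 14752484). Next came Capr, which encodes an RNA-binding protein (3L, 18673115 to 18673283), CG8613 (2R, 14352131 to 14352296) and Daxx, a histone chaperone gene, with Sec61alpha and lncRNA:CR45463 (2L, 6480810 to 6480977). Sumo, the gene of the small ubiquitin-like modifier (2L, 6967560 to 6967745), Creld (2L, 102247 to 102471) and Pym (2R, 23856852 to 23857095) completed the first 10.

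The remaining strong promoter regions were at milt, whose product links mitochondria to motor proteins (2L, 7049028 to 7049271), and at hts, the adducin gene, with CalpA (2R, 19424895 to 19425030). Others were at RpL32, a ribosomal protein gene, with CG7943 (3R, 30046099 to 30046342), CtsF, a cathepsin gene, with asRNA:CR44019 (3R, 5251719 to 5251880), and Pcif1 (3L, 20786148 to 20786301). Scsalpha1, which encodes a subunit of succinyl-CoA synthetase, followed (3L, 3814099 to 3814273), with EndoGI and PRL-1 (2L, 16257505 to 16257848). The list closed with CG11030 (2L, 5724530 to 5724699), kug, an atypical cadherin gene (3L, 20006220 to 20006563), and CG2924 (X, 2270701 to 2270856). The word CGATA lay within 100 bp of the summit in 18 of these 20 regions, all but org-1 and milt.

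The genes on the preset list named ecdysteroid synthesis, which also holds Cyp18a1, a gene of ecdysteroid breakdown, lacked peaks in the thresholded lists. The list is short, so its count does not separate it from other genes, and the chromatin came from whole embryos, not from the gland alone. None of the 10 listed genes (nvd, sro, spo, spok, Cyp6t3, phtm, dib, sad, shd and Cyp18a1) had a peak in any of the 3 replicate lists, either within 500 bp of a start or within the gene (0 of 10 against 5.37% of other protein-coding genes at promoters, Fisher's exact test, adjusted p = 1). Among 13 genes listed as regulators of the ecdysteroid gland (1 of 13 with a consensus summit at a start, exact adjusted p = 0.939), ecd had a consensus summit at its start (3L, summit 2265868, 11 bp from the start) and peaks in all 3 lists. The zinc-finger gene woc had peaks in all 3 lists in an intron (3R, summit 27263532, 523 bp from the nearest start). In mld itself, replicates 1 and 2 had peaks in a coding exon (3R, summits 24620453 and 24620002), which did not overlap. Replicate 3 had none in its thresholded list, with a lowest IDR of 0.0108 over mld in its ranked list. The mld peaks of replicates 1 and 2 ranked 987 and 857 by signal in their lists. The flies also carried mld sequence in the transgene, and whether this contributed to the peaks was not tested. Oatp74D, the ecdysone importer gene, had a peak in 1 list, and ouib, vvl, kni, Npc1a, Start1, tor, Ptth, Fdx1 and dare had peaks in 0 lists. In the ranked lists before the threshold, the lowest IDR over all 3 replicates was 0.376 at nvd, 0.413 at spok and 0.353 at sro.

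Of the 19 gene lists, 3 passed the test at promoters. A consensus summit lay within 500 bp of a start for 101 of 290 tRNA genes (34.8%, 29.4 to 40.6), against 4.43% of the other annotated genes (Fisher's exact test, odds ratio 11.5, adjusted p = 1.34e-57). The tRNA genes with the best-ranked summits were tRNA:Leu-AAG-1-3 (2R, summit 17145387), tRNA:Gly-GCC-1-9 and tRNA:Trp-CCA-2-2, which share a region (2R, summit 18639680), and tRNA:Gly-TCC-1-2 (3R, summit 7130993). These 101 genes were served by 64 regions. At an IDR of 0.001 the count fell to 49 of 290 (16.9%, exact adjusted p = 1.03e-26). Counting only the first gene of each tRNA cluster, 52 of 175 had a consensus summit (29.7%, 23.1 to 37.1). No summit lay at any of the 27 tRNA genes whose sequence occurs once in the arms and that have no other tRNA gene within 1000 bp (0%, up to 12.8%).

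Cell cycle genes had summits more often than other protein-coding genes, at 6 of 22 (27.3%, 10.7 to 50.2) against 5.33% (Fisher's exact test, odds ratio 6.66, adjusted p = 0.00788). The best-ranked were the cyclin gene CycB (2R, summit 22807037), the kinase gene Cdk2 (3R, summit 20735558), geminin, an inhibitor of replication licensing (2R, summit 6656408), and the transcription factor gene E2f2 (2L, summit 21156259). The call was lost with the list the authors named conservative (7 of 22, exact adjusted p = 0.123) and at an IDR of 0.001 (2 of 22, adjusted p = 0.568). Replication-dependent histone genes had summits at 0 of 111, against 5.41% (exact adjusted p = 0.0289). However, only 5 of the 111 had a peak of any rank within 500 bp of a start, and the call was lost when genes without such a peak were left out (exact adjusted p = 1). It was also lost with a promoter window of 200 bp, at an IDR of 0.001 (exact adjusted p = 0.0639 and 0.568), and over gene bodies against lists matched on length (adjusted permutation p = 0.705).

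The other 16 lists did not pass. Lists of developmental regulators and their targets had few consensus summits or none, with 0 of 23 ecdysone response genes, 0 of 12 homeotic genes, 0 of 25 neural regulators, 0 of 18 mesoderm and muscle genes, 0 of 11 endoderm and fat body genes, 0 of 16 cuticle and chitin genes, 0 of 15 Wnt pathway genes and 1 of 23 segmentation genes. With 11 to 25 genes each, these counts had adjusted p-values of 0.939 or 1 and do not separate these lists from other genes. The conservative list had summits at 21.7% of the ecdysone response genes, 33.3% of the homeotic, 26.7% of the Wnt pathway genes and 12% of the neural regulators, and none of these passed (exact adjusted p = 0.549, 0.227, 0.492 and 1). That list is longer, with 1970 peaks, so its shares are not comparable with the shares of genes with a consensus summit. The counts were 2 of 16 for the Notch pathway, 1 of 15 for heat shock genes, 2 of 23 for chromatin and insulator genes, 3 of 32 for snRNA genes and 7 of 269 for snoRNA genes, which passed as lower in the conservative list (exact adjusted p = 0.0103). Ribosomal protein genes had summits at 6 of 92 (6.52%, 2.43 to 13.7, exact adjusted p = 0.939). Without replicate 2 this became 10 of 92 (exact adjusted p = 0.470) and without replicate 3 it became 15 of 92 (odds ratio 2.68, adjusted p = 0.00855). In the conservative list it was 28 of 92 (odds ratio 2.58, exact adjusted p = 0.000563). Leaving out replicate 2 also moved the counts to 6 of 32 for snRNA genes (exact adjusted p = 0.0664), 2 of 15 for heat shock genes, 2 of 15 for the Wnt pathway (adjusted p = 0.654 for both) and 1 of 23 for ecdysone response genes (adjusted p = 1).

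**Figure D2:**
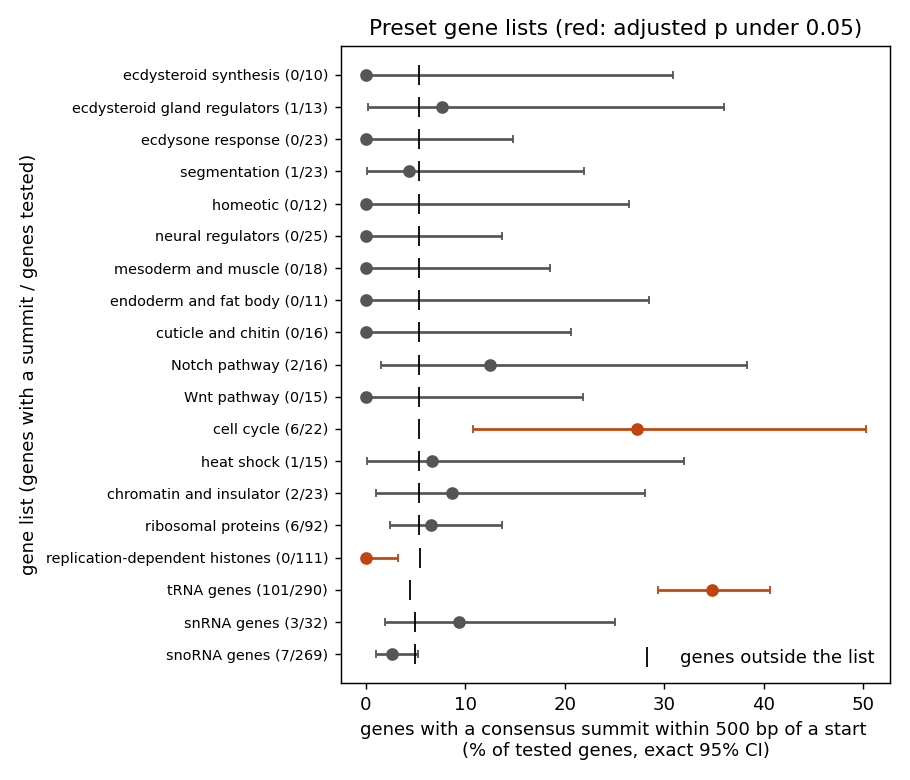
Share of the genes of each preset list that have a consensus summit within 500 bp of a start (horizontal axis, %, points with exact 95% intervals, red where the adjusted p is under 0.05), with the share among genes outside the list as a black tick. The tRNA genes stand at 34.8% and the cell cycle genes at 27.3%.

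The word CGATA, recognised by the insulator protein BEAF-32, and the longer DNA replication-related element TATCGATA were concentrated at the summits. CGATA lay within 100 bp of 516 of 620 summits (83.2%, 80.0 to 86.1). In the windows upstream and downstream by genome coordinate the shares were 24.7% and 20.3% (exact McNemar test, adjusted p = 1.22e-80). TATCGATA lay at 210 summits (33.9%, 30.1 to 37.7), against 0.645% and 0.484% (exact adjusted p = 3.62e-57). In the lists of single replicates, CGATA was found at 76.6% ± 3.86 and TATCGATA at 29.8% ± 1.92 of the peaks (SD, n = 3). The highest share of CGATA per 20 bp was 41.0%, in the bin just left of the summit.

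The M1BP word GGTCACACT was also more frequent at summits, at 4.35% (2.89 to 6.27) against 0.161% and 0.484% (exact adjusted p = 1.52e-05). E-boxes (CANNTG) were less frequent, at 56.6% (52.6 to 60.6) against 66.8% and 67.7% (exact adjusted p = 0.000993). AGGTCA, the word of the ecdysone receptor, was found at 2.58% (1.48 to 4.16) of summits against 5.97% and 5.48% (exact adjusted p = 0.0332), and runs of 8 A at 12.6% (10.1 to 15.5) against 6.61% and 6.45% (adjusted p = 0.00152). Neither of these last calls passed against random windows matched on GC content and on lying within 500 bp of a start or not (Fisher's exact test, adjusted p = 0.0528 and 0.295). Distance within these 500 bp was not matched. For AGGTCA the odds ratio was 0.418 (95% interval 0.214 to 0.779) and 0.457 (0.233 to 0.861) against the flanks and 0.569 (0.314 to 0.966) against the matched windows, 4.45% of which held it. These intervals overlap. For runs of 8 A the odds ratio fell from 2.03 (1.35 to 3.10) and 2.09 (1.38 to 3.19) to 1.17 (0.889 to 1.53), because 10.9% of the matched windows held such a run. Both calls were also lost at an IDR of 0.001 (exact adjusted p = 0.104 and 0.402) and with windows of 50 bp either side (1.13% and 3.71% of summits, exact adjusted p = 0.766 and 1). The words for GAF, Zelda, the palindromic E-box, the initiator, the TATA box, AP-1, GATA factors and CA repeats did not pass against the flanks. Against the matched windows, the GAF word, the initiator and CA repeats passed as lower and the palindromic E-box as higher (exact adjusted p = 0.0416 each), and the long GAF word as lower (exact adjusted p = 0.0468). The GAF word also passed as lower without replicate 1, 2 or 3 (exact adjusted p = 0.0133, 0.0446 and 0.00969), and the Zelda word did in the conservative list (exact adjusted p = 0.0383). Among 8161 tested 7-mers, 225 passed, 161 higher and 64 lower at summits, and 43 of the 225 contained CGATA or its reverse complement. The 5 with the largest ratio all contained CGATA or its reverse complement. They were CCTATCG at 19.4% of summits, ACTATCG at 39.2%, CTATCGA at 47.1%, ATCGATA at 63.2% (3.23% and 2.74% in the flanks) and AGTATCG at 15.2%.

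**Figure D3:**
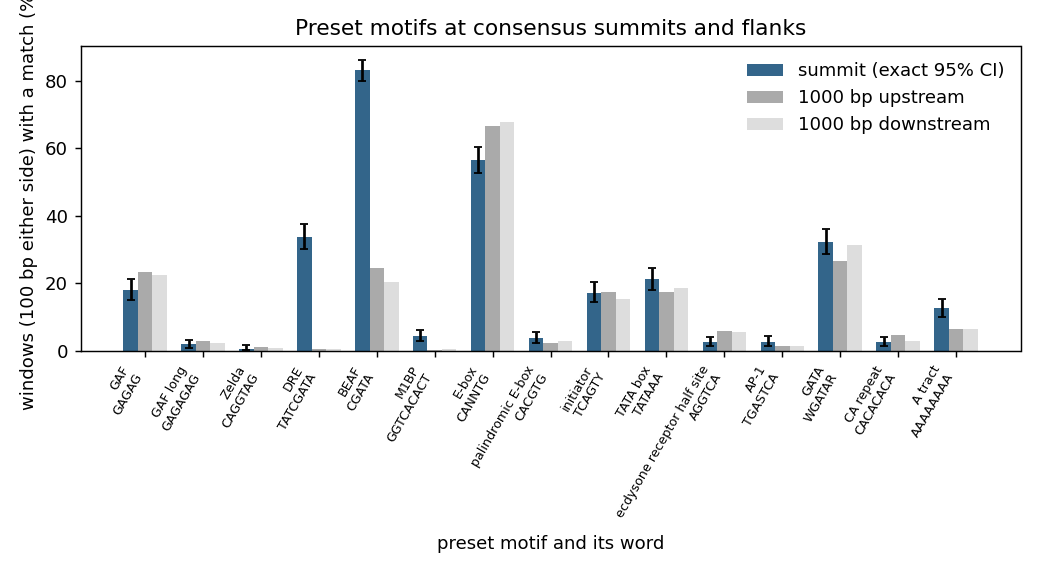
Share of windows with each preset word (vertical axis, %) at consensus summits (blue, exact 95% intervals) and at the windows 1000 bp upstream (dark grey) and downstream (light grey) by genome coordinate. CGATA reaches 83.2% at summits and 24.7% and 20.3% in the flanks.

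**Figure D4:**
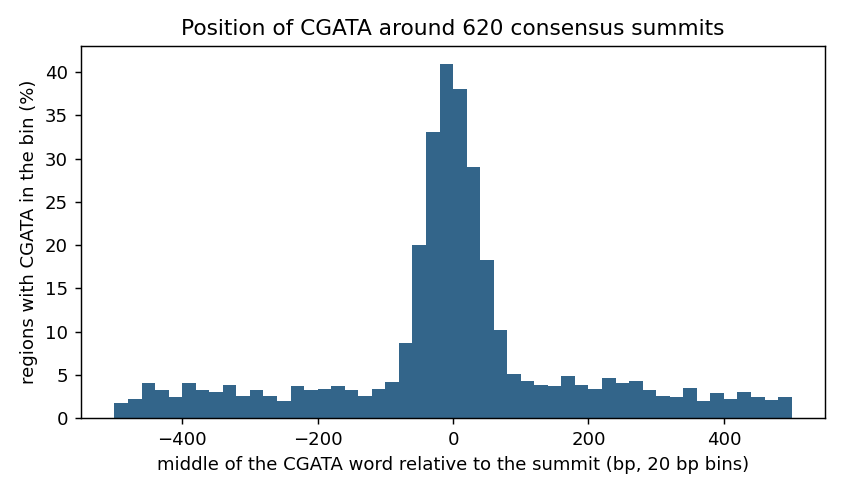
Share of the 620 consensus regions with a CGATA word (vertical axis, %) in each 20 bp bin from 500 bp left to 500 bp right of the summit (horizontal axis, bp). The share peaks at 41.0% beside the summit.

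The lists deposited for the whole series were made from the alignments of the same 3 samples, per the sample records, so their overlap with the consensus is no independent check. The conservative list had 1970 peaks and held 616 of the 620 regions (99.4%, 98.4 to 99.8). The other lists had 2996, 1815 and 1554 peaks and held 620, 617 and 615 regions. At promoters were 88.4% of the peaks of the conservative list on the arms, and 75.5%, 88.7% and 88.8% of those of the others.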

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

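The tests in this part were chosen after the data had been seen. In the ranked lists, 27 regions reached a global IDR of at most 0.01 in all 3 replicates and were absent from the thresholded lists, which made them a signal outside the lists the comparisons used. Of these, 25 lay on the arms, 23 of them at promoters and 18 with CGATA within 100 bp of the summit. The strongest was at the start of osa, a chromatin remodelling gene (3R, 17718294 to 17718457), with signals of 205, 164 and 144 in replicates 1, 2 and 3. Others were at kibra (3R, 14724261 to 14724388), InR, the insulin receptor gene (3R, 21619102 to 21619445), and a cluster of tRNA:Glu genes on 2R. Adding back all peaks that the thresholded lists lacked at this IDR gave 647 consensus regions. The sources do not state why the peaks were left out, and no explanation was tested.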

How the results depend on the processing

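The IDR values of 0.001 and 0.05, the return of the peaks left out and the count of 1 tRNA gene per cluster were chosen after the data had been seen. The overlap of lists, the promoter share (85.6% to 97.6%) and the calls for tRNA genes, CGATA, TATCGATA, M1BP, E-boxes, 2R and 3L kept their direction and their side of the threshold under all alternatives run for them. At an IDR of 0.001 the replicates had 740, 435 and 596 peaks, the consensus 296 regions and 1 gene list passed. At 0.05 the replicates had 2334, 1589 and 2080 peaks. Against GC- and start-matched windows 442 7-mers passed, 156 of them also in the main test, and the cause was not tested. Of 28 values that turned in direction, 24 were past the threshold neither in the main test nor under the alternative, and 4 were past it in at least 1 of these. With protein-coding starts only, non-coding exons held 7.58% of summits, since starts of non-coding genes no longer counted as promoters. The long GAF word was higher at summits in the conservative list (4.42%), and the initiator was lower than in matched windows (17.3%). Runs of 8 A in windows of 50 bp either side (3.71%) no longer differed past the threshold (exact adjusted p = 1). The cause was not tested. Over all alternatives, calls for single lists, words, classes or arms were lost in 18 values, from 7 results, and gained in 13, from 8 results. Lists of non-coding genes could not be tested with protein-coding starts only. No paired analysis was possible because there is 1 group. Read depth is unknown, which limits every statement on missing peaks.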

Other observations

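The tests of gene families, divergent starts, isotypes, the CGATA share of tRNA regions and tRNA genes away from others, and the comparisons with ribosomal protein genes and of org-1 with CGATA, were chosen after the data had been seen. Families were picked by gene symbol, after regions such as that at Rpn6 were known, and 13 were tested. Nuclear pore proteins had consensus summits at 5 of 21 starts (23.8%, Fisher's exact test, odds ratio 5.55, adjusted p = 0.0141), Rab GTPases at 6 of 31 (19.4%, adjusted p = 0.0141) and translation initiation factors at 8 of 44 (18.2%, adjusted p = 0.0136). Proteasome subunits had them at 6 of 40 (exact adjusted p = 0.0408) and mitochondrial ribosomal proteins at 10 of 73 (adjusted p = 0.0141). When the genes at regions seen by name beforehand were left out, the call for proteasome subunits was lost (4 of 38, exact adjusted p = 0.186), and the other calls held (largest exact adjusted p = 0.0415). The odorant, gustatory and ionotropic receptors had 0 of 179 (exact adjusted p = 0.00103). Cuticle proteins (0 of 70), odorant-binding proteins (0 of 51), cytochrome P450 enzymes (1 of 85), aminoacyl-tRNA synthetases (2 of 32), Integrator subunits (1 of 11), replication licensing proteins (0 of 12) and vacuolar ATPase subunits (1 of 33) did not pass.

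Of 531 consensus regions with a protein-coding start, 195 had the starts of a divergent gene pair within 500 bp of the summit (36.7%, 32.6 to 41.0), against 24.7% of places within 100 bp of 1 random start of each protein-coding gene (Fisher's exact test, odds ratio 1.77, p = 1.42e-09). This compares regions with genes, and whether the summits lie between the starts was not tested. Among the 22 tRNA isotypes of the annotation, 20 had at least 1 gene with a summit, and no isotype differed from the rest after adjustment. Of the snRNA genes with a summit, 2 encode U6 and 1 encodes 7SK, and their regions ranked from place 28 to 173.

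The concentration of CGATA at summits was set against the composition of promoters and against promoter regions below the threshold. Random windows matched on arm, GC content and lying within 500 bp of a start or not held CGATA in 26.7%. This is far below the 80.0% lower bound at summits, which argues against composition of promoter windows as the whole cause. Distance within these 500 bp was not matched, and the summits lay a median of 40 bp from a start. A share particular to sequence that near a start was therefore not tested. Among the 1000 strongest promoter regions that all ranked lists held without reaching an IDR of 0.05, 34.2% (31.3 to 37.2) had CGATA, which argues against a property of every promoter peak. Signal that promoters with consensus summits give with any antibody stays open, because the control libraries were not analysed here. No biological explanation was tested.

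For the tRNA genes, high transcription in general was examined first: ribosomal protein genes, which are highly transcribed, had summits at 6.52% (2.43 to 13.7), below the 34.8% (29.4 to 40.6) of tRNA genes, and the intervals stayed apart without replicate 3 (16.3%, 9.42 to 25.5, against 36.9%, 31.3 to 42.7) and in the conservative list (30.4%, 21.3 to 40.9, against 52.8%, 46.8 to 58.6). In these settings ribosomal protein genes also passed against other genes, and transcription was not measured, so a part due to high transcription cannot be told apart from binding. Regions at tRNA starts held CGATA in 18.8% (10.1 to 30.5), against 90.6% of the others, so neighbouring CGATA promoters do not account for most of them. Reads shared between identical copies cannot be told apart from binding: summits lay at 23.1% (12.5 to 36.8) of the 52 tRNA genes with a unique sequence, but all 12 of these had another tRNA gene within 1000 bp, so the bound set beforehand could be met by a neighbour's signal. Over all tRNA genes, 12 of 52 unique and 89 of 238 repeated ones had a summit (Fisher's exact test, odds ratio 0.502, p = 0.0546), which did not pass. Away from other tRNA genes, 0 of 27 unique and 17 of 80 repeated tRNA genes had a summit (Fisher's exact test, p = 0.00572), which may reflect copy number or differences between these genes, and signal that any antibody gives there stays open without the control libraries.

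The strongest region, in org-1, has 0 CGATA words over its whole length, the nearest lying 281 bp from its summit, which argues against a word within the region as its source. The region holds an array of 7 copies of GGTTAAAG (X, 8452314 to 8452405), which may draw the signal. No other place on the arms has at least 3 copies within 200 bp, so 0 other arrays with a peak says nothing, and the array cannot be told apart from other features of this region. Signal that any antibody gives at this region stays open without the control libraries, and no biological explanation was tested.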
